A study of Mus musculus with 2 samples.

How the data were processed

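Total RNA from the hippocampus of ICR mice, 1 sample from sham and 1 from 5/6Nx mice 8 weeks after the operation, was amplified to cRNA, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The extraction protocol in the labels speaks of cells, and the source is given as hippocampus, so the samples were taken to be hippocampal tissue. How the tissue was dissected and whether blood was flushed from it are not given in the sources used here. The deposited scanner output of each array holds linear intensity values per spot. Per the file headers, the authors extracted it with Feature Extraction 10.7.1.1 under the protocol for 1-colour expression arrays, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed intensity is background-subtracted and spatially detrended within each array, spots near background carry surrogate values, and nothing was normalized between arrays. The deposited table of the series holds 1 linear intensity per probe, and its scale was settled from the values. Its 2 columns have the same sorted values within 0.0323% and a median of 124 each, as quantile normalization by the authors gives. Each column correlated at 1.000 with its own array and at 0.983 with the other over 55674 probes, on the log2 scale. All of its columns were mapped to a sample, and it was used as an alternative.

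From the scanner output, control spots and spots with an outlier flag (105 in sham, 97 in 5/6Nx) were left out. The log2 of the processed intensity of each spot was taken relative to the array's 75th percentile, and replicate spots of a probe were averaged. Probes were named through a table of mouse RefSeq genes (GRCm38.p6), which was used for names only: 27235 probes matched by accession, 3581 by symbol and 565 by synonym, and 24300 kept the name in the scanner file. Probe coordinates are those of the scanner files, on mm9. A gene was represented by the probe with the highest mean log2 value among its probes well above background on at least 1 array, and it counted as measured when that probe was well above background on both. For a gene above background on 1 array only, the difference is given as a bound, the bright value against the higher of the other array's lowest value well above background and the dim probe's own value. A gene is called higher or lower at a difference of at least 2-fold. This threshold is a size and not a test.

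The 48 gene lists (19 of cell types and 29 of pathways), the alternatives and the rule for named genes were fixed before the data were examined. Named genes had an ordinary gene symbol and all measured probes in 1 direction. The rule took the 8 highest and 8 lowest differences among genes above the median signal, the 4 highest and 4 lowest below it, the 3 largest bounds in each direction, and the 2 to 4 members of each described list with the largest absolute difference. Genes named outside this rule are said to be so where they appear, Xist is named only as a transcript of its fixed list that was not measured, and some genes that it takes are not reported here. The median difference of a list was ranked among 10000 random lists of equal size, drawn from the measured genes within 20 bins of mean signal, and lists with at least 5 measured members were ranked. Members were matched under current symbols. No p-value was computed, since each group holds 1 array and the number of arrays limits the precision.

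The calculation was tested on simulated data. For 25917 genes with normal noise and 200 genes altered by known folds, the computed differences had a largest error of 0. The error was taken against the entered alteration plus noise, so it checks the arithmetic and not the recovery of the folds. At the 2-fold threshold 18% of the genes altered 1.5-fold, 32% of those altered 2-fold, 94% of those altered 3-fold and 100% of those altered 4-fold were counted in the right direction, and 1.95% of unaltered genes were counted. The noise had an SD of 0.43, taken from the interquartile range of the real differences and smaller than their SD of 0.60, so the share of unaltered genes counted is no estimate for the real arrays. A gene altered exactly 2-fold lies at the threshold, so noise decides its call. The simulated values entered with 1 probe per gene and already normalized, so normalization and the choice of probe were not tested. Of 200 random lists of 15 genes, 5% fell outside the middle 95%, and after a shift of 0.5 log2 96.5% were found on the right side. These lists were drawn at random from the same genes, so the 5% does not hold for lists whose members vary together.

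The alternatives were quantile normalization, scaling to the median, removal of the trend with signal by lowess (span 0.3), normexp background correction with an offset of 50, no background subtraction, the authors' normalized table, 3 other filters on dim probes, the mean over probes, outlier spots kept, thresholds of 1.5-fold and 3-fold, and 10 bins for random lists. Scaling to the 8 E1A spike-in probes well above background, and leaving out list members shared with the choroid plexus, leptomeningeal and blood cell lists, were added after the data were seen. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.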

Results

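Gene expression was measured in the hippocampus of ICR mice, an outbred laboratory strain, 8 weeks after a sham operation or 5/6Nx. 5/6Nx is the usual short form for 5/6 nephrectomy, a surgical model of chronic kidney disease in which most of the kidney tissue is removed. Total RNA was labelled with Cy3 and hybridised to 1-colour 60-mer arrays, with 1 array for the sham sample and 1 array for the 5/6Nx sample. There were no replicates, so no test between the groups was possible and every difference below describes these 2 arrays. The labels do not say how many animals gave the RNA of each array. Each array held 59305 non-control spots for 55681 probes. In the sham sample 43138 spots (72.7%) were well above background and in the 5/6Nx sample 43016 (72.5%), and no spot was saturated. The 75th percentile of the processed intensity was 1452 in sham and 1263 in 5/6Nx. The 2 arrays lay on 1 slide and were read in 1 scan, so slide and scan did not differ between the groups.

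The comparison asks which hippocampal transcripts differ in level between 5/6Nx and sham mice. Differences are given as 5/6Nx minus sham on the log2 scale, after each array was set to its own 75th percentile. Markers of the choroid plexus epithelium, the tissue that secretes cerebrospinal fluid, were higher in the 5/6Nx sample: all 17 measured markers lay above 0 and 16 were at least 2-fold higher, with a median of 2.20. Markers of blood cells were lower, with a median of -3.55 over 12 measured genes, among them haemoglobin genes. Second lists of leukocyte and platelet genes (0.00077) and of red cell genes (-0.08) lay within the range of random lists. Markers of leptomeningeal fibroblasts, cells of the membranes around the brain, were lower as well, with a median of -1.99 over 13. Among pathways, glucocorticoid-regulated genes were higher (median 0.71), while genes of cholesterol synthesis (-1.05), the interferon response (-0.997), the unfolded protein response (-0.84), heat shock (-0.71) and antigen presentation (-0.66) were lower. Markers of GABAergic interneurons (-0.50) and of CA1 pyramidal cells (-0.51) were lower, and markers of CA2 and CA3 pyramidal cells (0.46) and of dentate granule cells (0.35) were higher.

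In total 27564 genes and transcripts were well above background on at least 1 array and 25917 were measured on both. Of these, 1268 were at least 2-fold higher and 852 at least 2-fold lower in 5/6Nx, together 8.18% of the genes measured, and 59.8% of the 2-fold differences were higher. Restricted to genes with a symbol in the reference table, 733 were higher and 704 lower. A further 748 genes were above background in 5/6Nx only and 853 in sham only, and for 46 more both arrays had a probe above background but not the same one. The median difference of all measured genes was 0.05 with an SD of 0.60, and Pearson's correlation between the 2 arrays was 0.983 across genes, which are not independent replicates. The split depended on the scaling: 49.2% of the 2-fold differences were higher after quantile normalization, 47.9% after removal of the trend with signal, 49.4% in the authors' own normalized table and 36.2% when the arrays were set to their spike-in controls. The spike-in scaling moved the median of all genes from 0.05 to -0.16, so differences are read relative to the other genes. Replicate spots of 1 probe had a median SD of 0.05 on each array, and different probes of 1 gene had a median SD of 0.20 in their difference. These 2 spreads are technical and leave out the variation between animals.

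**Figure D1:**
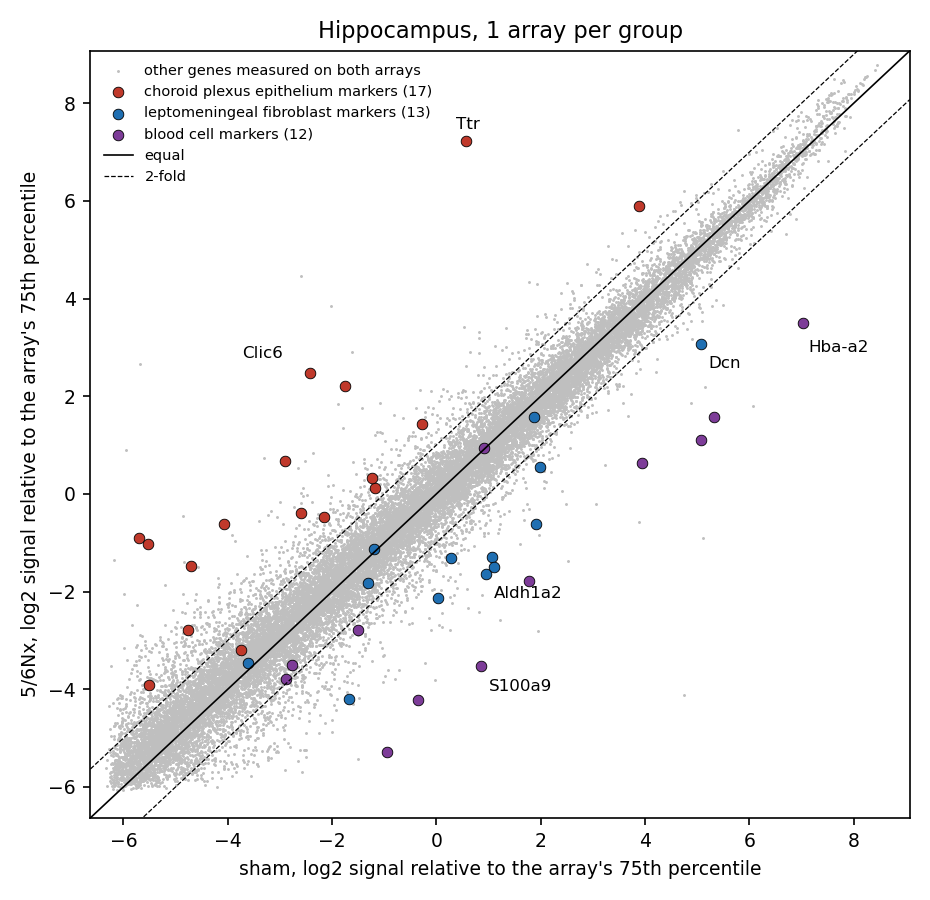
Log2 signal of each gene measured on both arrays, relative to the array's 75th percentile, in sham (horizontal axis) and 5/6Nx (vertical axis), with the line of equality and dashed lines at 2-fold. The 17 choroid plexus markers lie above the line of equality, and 11 of the 13 leptomeningeal and 11 of the 12 blood cell markers lie below it.

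Among genes above the median signal, Syt10, which encodes a synaptotagmin of regulated secretion, had the highest difference at 7.05 (132-fold), from a probe signal of 241 in sham and 27773 in 5/6Nx. It was followed by Ttr, which encodes transthyretin, the carrier of thyroid hormone and retinol secreted by the choroid plexus, at 6.66 (101-fold). The signal of Ttr was 2160 in sham and 189501 in 5/6Nx, from a probe on chromosome 18 between 20828519 and 20828577 of the mm9 build. Clic6, an intracellular chloride channel protein, stood at 4.90, Ecrg4 at 4.52, the folate receptor gene Folr1 at 3.97, Ugt1a6b at 3.74 and Spaca6 at 3.18. The lowest values were those of Neil2, a DNA glycosylase of base excision repair, at -6.01 and of Tgtp2, an interferon-inducible GTPase, at -4.75. They were followed by the histone genes H4c4 (-4.45) and H4f16 (-3.89) and the haemoglobin genes Hbb-bt (-3.97), Hba-a1 (-3.73), Hbb-bs (-3.57) and Hba-a2 (-3.53). Signal for Neil2 was 50300.2 in sham and 677 in 5/6Nx, and for Hba-a2 189146 and 14251. The haemoglobin and histone genes have near-identical copies, so these probes can also bind transcripts of other members. Of the genes named in this paragraph only Folr1 and Spaca6 had more than 1 measured probe, and the other probe of Spaca6 stood at 0.95.

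Among dimmer genes the highest differences were those of Tex22 (4.82), the potassium channel subunit gene Kcne2 (4.81), the bicarbonate transporter gene Slc4a5 (4.51) and Cltrn (4.41). The lowest were those of S100a9 (-4.39) and S100a8 (-4.34), which encode calprotectin of neutrophils, of Insrr (-3.94) and of Alas2 (-3.87), the haem synthesis enzyme of erythroid cells. Of the genes above background in 5/6Nx only, Sult1c2 was at least 63.2-fold higher, Prm1 at least 40.0-fold and Krt12 at least 38.9-fold. Of those above background in sham only, Olfr134 was at least 17.7-fold lower, Olfr486 at least 11.998-fold and H2-Q1 at least 10.4-fold. Of the 395 genes with several measured probes and a mean difference of at least 2-fold, 379 (95.9%) had all probes in 1 direction, against 64.8% of all genes with several measured probes. Selection on the mean of the same probes favours such agreement.

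**Figure D2:**
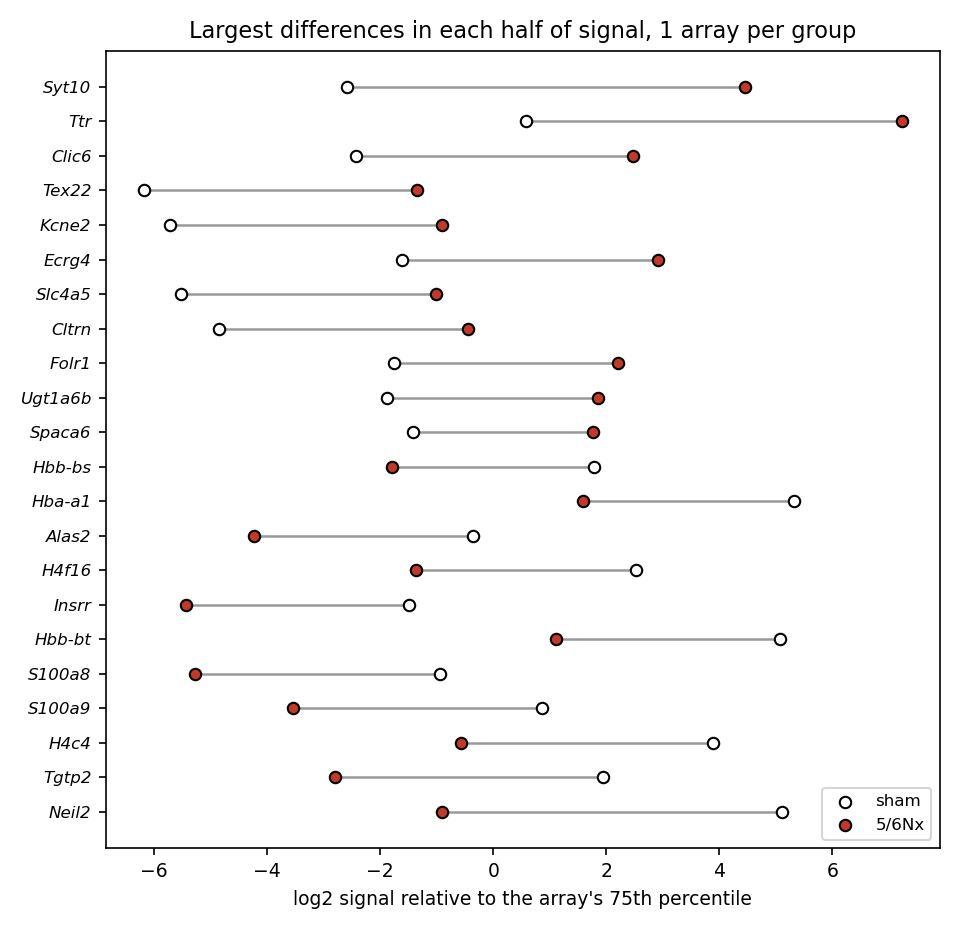
Log2 signal relative to the array's 75th percentile in sham (open circles) and 5/6Nx (filled circles) for 22 genes, the 7 highest and 7 lowest differences above the median signal and the 4 highest and 4 lowest below it, ordered by difference. Syt10 at the top differed by 7.05 and Neil2 at the bottom by -6.01.

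Each gene list was described by its median and by the place of that median among 10000 random lists of equal size and matched signal, as a description of these 2 arrays. Of 47 ranked lists, 26 lay outside the middle 95% of the random medians, 7 above and 19 below. By chance 2.35 would be expected if the genes of a list varied independently. Members of a list can vary together and some lists share genes. The number expected can therefore be larger without an effect of the group, and the 26 lists are not separate results. The choroid plexus list lay above all 10000 random medians, led by Ttr (6.66), Clic6 (4.90), Kcne2 (4.81) and Slc4a5 (4.51). The blood cell and leptomeningeal lists lay below all of them. Of the 12 blood cell markers 9 were at least 2-fold lower, led by S100a9, S100a8, Hbb-bt and Alas2. Of the 13 leptomeningeal markers 9 were at least 2-fold lower, among them the organic anion transporter gene Slc22a6 (-2.61), the retinaldehyde dehydrogenase gene Aldh1a2 (-2.59), the transporter gene Slc6a13 (-2.53) and Col3a1 (-2.52).

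Markers of the hippocampal subfields differed in direction. CA1 markers had 4 of 10 members at least 2-fold lower, including Ccn3 (-1.34) and Wfs1 (-1.12). Of the 10 markers of CA2 and CA3, 8 lay above 0, with Map3k15 at 1.16 but Coch at -1.81, and the dentate granule list was led by Pdzd2 (1.06) and Tdo2 (0.94). Of 15 GABAergic interneuron markers 14 lay below 0, including Cort (-1.17), the parvalbumin gene Pvalb (-1.03) and the somatostatin gene Sst (-0.92). The pan-neuronal list had a median of -0.21, with the tubulin gene Tubb3 at -1.48 and the RNA-binding protein gene Elavl4 at -1.03. The oligodendrocyte list had a median of -0.30, with Opalin at -2.30 and Ugt8a at -1.87. Medians of the lists for glutamatergic neurons (0.16), astrocytes (-0.13), oligodendrocyte precursors (-0.14), microglia (0.04), endothelium (0.15), mural cells (-0.04) and ependyma (0.09) lay within the range of random lists. So did those for the neighbouring thalamus and habenula (-0.11) and striatum (0.02). Within the astrocyte list Gfap, the intermediate filament of astrocytes, was higher by 1.12 and the water channel gene Aqp4 had a value of -0.83. The 4 measured Y-linked transcripts, too few to rank, had a median of 0.11, with Kdm5d at 0.30 and Eif2s3y at 0.11, and Xist was not well above background on either array. Outside the rule for named genes, the 2 measured probes of Uty differed in direction (0.12 and -0.69).

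Glucocorticoid-regulated genes had 7 of 21 members at least 2-fold higher and 0 lower. They were led by the cell cycle inhibitor gene Cdkn1a (1.90), the kinase gene Sgk1 (1.60), Plin4 (1.47) and Pdk4 (1.43), and the list median lay above all 10000 random medians. The hypoxia and erythropoietin list (median 0.34) had 4 of 19 members at least 2-fold higher, among them the adrenomedullin gene Adm (2.40) and Ddit4 (1.32). The complement and phagocytosis list (0.32) held Lgals3 (1.39) and the complement gene C4b (1.24) among its higher members and the Fc receptor gene Fcgr1 (-2.70) among its lower ones. The extracellular matrix list (0.40) had 12 of 21 members above 0, whereas its fibrillar collagens Col3a1 (-2.52) and Col1a1 (-1.58) were lower together with the other leptomeningeal markers. Without the members it shares with the choroid plexus, leptomeningeal and blood cell lists, its median was 0.52.

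Of 18 genes of cholesterol synthesis and uptake 17 lay below 0 and 11 were at least 2-fold lower, led by the isomerase gene Idi1 (-1.75), Stard4 (-1.38) and Msmo1 (-1.34). Of 20 genes of the unfolded protein response 10 were at least 2-fold lower, including the endoplasmic reticulum chaperone and folding genes Sdf2l1 (-1.79), Pdia6 (-1.62) and Manf (-1.53). Of 13 heat shock genes 6 were at least 2-fold lower, including Hspb1 (-2.08), Hsph1 (-1.73) and Cryab (-1.72). Interferon response genes had 10 of 21 members at least 2-fold lower, led by Gbp2 (-2.94), Oas1a (-2.71) and Gbp3 (-2.67). Antigen presentation genes had 7 of 17 at least 2-fold lower, including the class II pathway genes H2-Aa (-1.96) and Cd74 (-1.49) and the immunoproteasome gene Psmb9 (-1.58). The medians of these 5 lists lay below all 10000 random medians, on the same array on which the blood cell and leptomeningeal markers were lower.

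Of 21 neuropeptide genes (median -0.65) 5 were at least 2-fold lower, led by the corticotropin-releasing hormone gene Crh (-1.56) and Grp (-1.32), and 2 were higher, led by the orexin gene Hcrt (1.33). Metabotropic glutamate receptors (-0.39) were led by Grm3 (-1.85) and Grm8 (-1.42), and GABA-A receptor subunits (-0.31) had 9 of 12 members below 0. The list of neurogenesis and proliferation (-0.32) had Tubb3 (-1.48) and Eomes (-0.95) as its lowest members. The immediate early list (-0.23) had Inhba (-1.34) and Nr4a2 (-1.29), and oxidative phosphorylation (-0.23) had Cox5a (-0.67) and Cycs (-0.60). The reactive astrocyte list (-0.24) had 5 of 17 members at least 2-fold lower and 2 higher, with Gbp2 (-2.94), the lipocalin gene Lcn2 (-2.63) and Hspb1 (-2.08) as its lowest. These lowest members also belong to the interferon, inflammatory and heat shock lists, and the astrocyte filament gene Gfap was among the 2 higher. The retinoid list (-0.22) held both the choroid plexus gene Ttr (6.66) and the leptomeningeal gene Aldh1a2 (-2.59), besides Crabp2 (-1.81) and Rbp4 (-1.32).

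**Figure D3:**
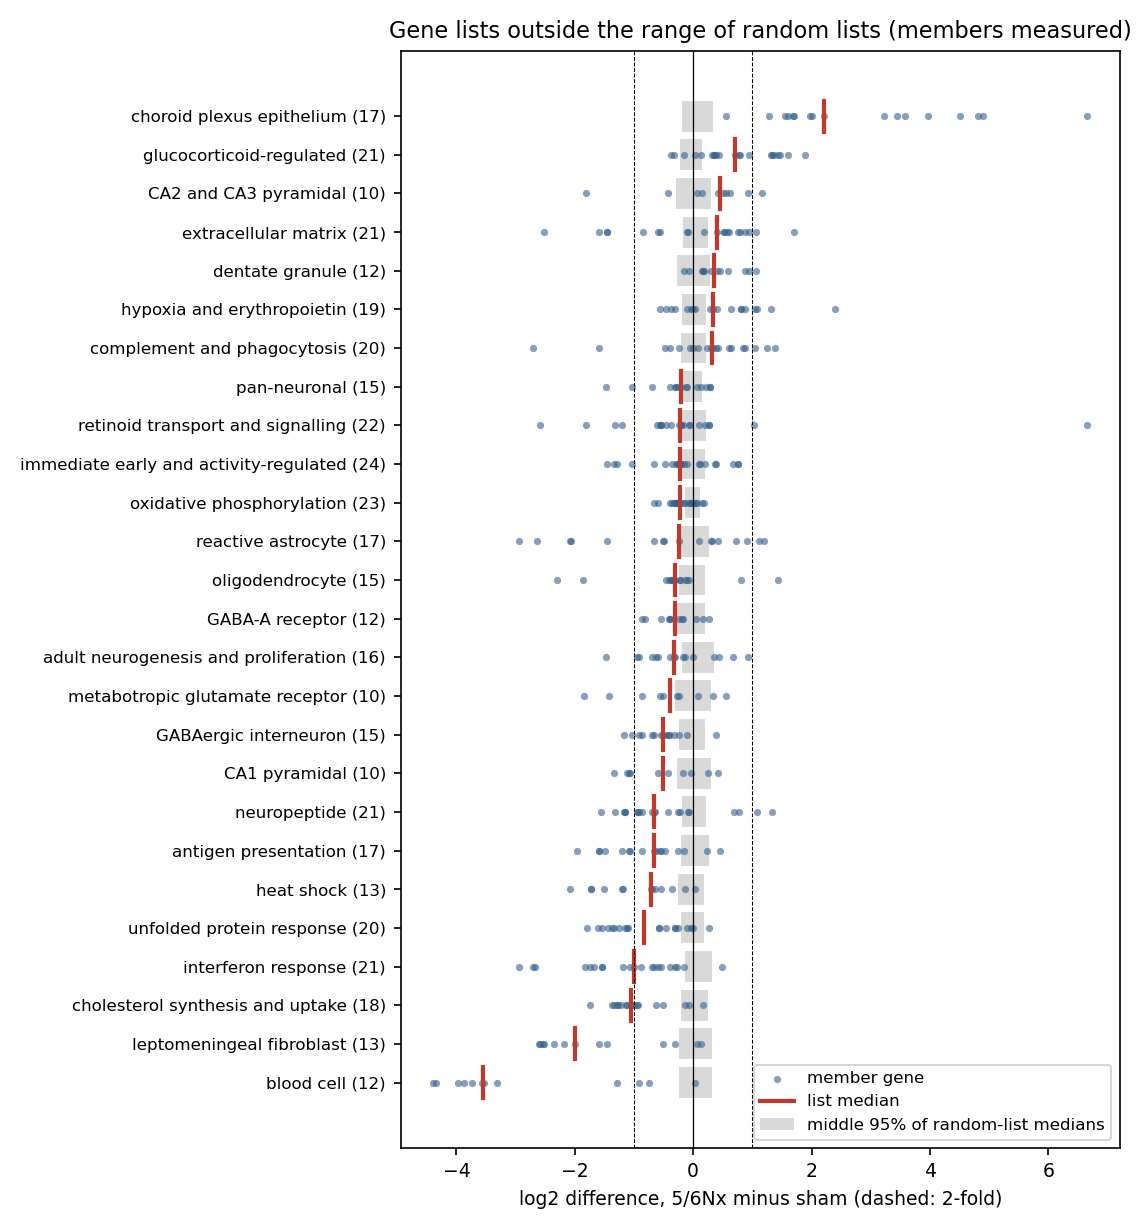
Log2 difference (5/6Nx minus sham) of each measured member (points) and the median (red bar) of the 26 gene lists outside the middle 95% of random-list medians (grey), with the number of members measured in brackets and dashed lines at 2-fold. Medians run from -3.55 for blood cells to 2.20 for choroid plexus.

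The remaining lists lay within the range of random lists, although several held single genes at least 2-fold apart. The renin-angiotensin list (0.26) had the angiotensin-converting enzyme gene Ace at 1.85 and the angiotensinogen gene Agt at 1.33, but the receptor gene Agtr1a at -1.16. The circadian clock list (0.15) had Ciart at 1.58 and Nr1d2 at 0.95, although the other probe of Nr1d2 stood at 0.015. The list of vitamin D, FGF23 and calcium genes (0.24) had the choroid plexus marker Kl at 1.28, and the list of barrier and solute transport (0.22) the leptomeningeal markers Slc22a6 (-2.61) and Slc6a13 (-2.53). Among ionotropic glutamate receptors (0.09) Grik3 was lower at -1.05, and the 2 probes of Gria2, a gene outside the rule for named genes, differed in direction (1.27 and -0.80), and among monoamine and acetylcholine receptors (-0.13) Chrm4 was higher by 1.16. The inflammatory list (0.10) had 2 of 21 members at least 2-fold higher and 4 lower, with Lcn2 at -2.63 and Il1b at -1.10. Medians were 0.02 for NRF2 and antioxidant genes, -0.04 for NADPH oxidase and nitric oxide genes, and 0.06 for the kynurenine list, in which Qprt was at -1.68. The list of synaptic plasticity kinases and scaffolds had a median of -0.01 and 0 of 22 members at least 2-fold apart, and cytosolic ribosomal proteins had -0.07 and 0 of 22.

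When only genes above the median signal were kept, 19 of the 26 lists stayed outside the range of random lists, and those lost were interferon response, reactive astrocyte, extracellular matrix, neurogenesis, metabotropic glutamate receptor, dentate granule and CA2 and CA3. The pan-neuronal list was lost when all probes of a gene were averaged and with both other background corrections, and the reactive astrocyte list when probes were averaged.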

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

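Each group has 1 array, so leaving out an array was not possible, and signal over background limits what dim probes show. No paired analysis was possible because each group has 1 array. The spike-in scaling and the lists without shared members were chosen after seeing the data. The 174 named or listed genes at least 2-fold apart kept their direction in all 1963 values under alternatives, and the 26 lists outside the random range kept their side under all 12 alternatives run on every list. Genes and lists were selected for their size on the same 2 arrays that the alternatives process again, which favours such agreement. Scaling to the median or to the spike-in probes moves all genes by 1 constant, too small to reverse a 2-fold difference and without effect on ranks. Keeping genes above the median signal, or above background on 1 array, reuses the same gene values. Agreement under these alternatives was therefore largely fixed in advance. Between 23 and 27 lists were outside under each alternative. Where a value below moved, the cause was not tested unless a filter or threshold itself sets it. Genes at least 2-fold higher and lower were 683 and 497 with normexp, 635 and 468 with no background subtraction, 2590 and 1668 with no filter, 319 and 305 above the median signal, and 799 and 1411 with spike-in scaling. They were 3549 and 2313 at 1.5-fold and 387 and 245 at 3-fold, and 1282 were lower with genes above background on 1 array included (1764 higher). With normexp and with no background subtraction, in this order, list medians were 2.05 and 2.05 for choroid plexus, -1.67 and -1.57 for leptomeninges, -3.15 and -3.06 for blood cells, -0.61 and -0.59 for interferon response, -0.72 and -0.69 for the unfolded protein response and -0.13 and -0.12 for neurogenesis. With genes above background on 1 array, and with no filter, the choroid plexus median was 2.72 both times and that of reactive astrocytes -0.49 and -0.37. Above the median signal, medians were 0.16 for CA2 and CA3, -0.65 for GABAergic interneurons, -2.17 for leptomeninges, -0.46 for the retinoid list, -0.31 for interferon response, -0.10 for reactive astrocytes, -0.26 for metabotropic glutamate receptors, -0.87 for neuropeptides, 0.048 for extracellular matrix and 0.19 for dentate granule cells. The complement median was 0.204 after quantile normalization and 0.205 in the authors' table, and that of extracellular matrix 0.25 with lowess, all still outside. Spike-in scaling set the lists and the random lists lower alike, by 0.217. With the mean over probes they were -0.13 for pan-neuronal, -0.30 for CA1, -0.054 for reactive astrocytes and -0.93 for heat shock. The extracellular matrix median without shared members was 0.52. Of 254 values of lists within the random range, 11 moved outside it: 5 of the monoamine and acetylcholine receptor list (to between -0.17 and -0.31), 4 above the median signal, among them the inflammatory list (-0.39), and 1 each of the renin-angiotensin list with normexp and the transport list with the mean over probes.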

Other observations

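All genes and families in this paragraph and the next were chosen after their values were seen. Of 15 measured guanylate-binding proteins and immunity-related GTPases, families of interferon-inducible genes, 8 were at least 2-fold lower in 5/6Nx and 1 higher, with a median of -1.50. Without the 3 members named above, 5 of 12 were at least 2-fold lower and the median was -0.52. The 1 higher member, Gbp6, had probes at 1.70 and -1.38, and Gbp5 had probes at 0.48 and -2.90, so the direction of both depends on the probe. Gbp4 stood at -3.24, Igtp at -2.96 and Irgm2 at -2.73. Of 36 measured replication-dependent histone genes 32 lay below 0, 11 were at least 2-fold lower and 1 higher (median -0.43), with H4c12 at -2.95 and H2bc6 at -2.82. The higher member was H4c8 (1.28), and H4c14, counted as lower, had probes at -3.01 and 0.21. Transcripts of these histone genes lack the poly(A) tail of other messengers, and their probes can bind several copies.

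Single genes outside the lists were picked for their large differences, so they cannot represent a group of genes. Whether their differences belong with those of the choroid plexus, leptomeningeal and blood cell markers was not tested. Higher in the 5/6Nx sample were the keratin gene Krt18 (3.22), Wdr86 (3.20), Wfdc2 (2.84), the cation channel gene Trpv4 (2.48), Depp1 (2.46), Etnppl (2.43) and Slc2a4 (2.07), which encodes the insulin-responsive glucose transporter. Lower were Lyve1 (-2.83), Prg4 (-2.75), Omd (-2.70), Foxc2 (-2.50), the platelet factor gene Pf4 (-2.40) and Fcrls (-2.39).

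Of the tests below, the second lists of choroid plexus, leukocyte and platelet, leptomeningeal and heat shock genes were written before their values were seen, and the other tests were chosen only after the result was seen. The choroid plexus markers were higher in 5/6Nx with a median of 2.20. A difference in Ttr alone is argued against by the other 16 markers, which had a median of 2.11. More choroid plexus in the 5/6Nx sample may account for the pattern, and a second list of 22 choroid plexus genes, all of them also above background in sham, had a median of 0.43 (percentile 99.98), between the values set in advance for and against it. A difference of expression within the choroid plexus after 5/6Nx stays open as well, since the markers spread with an SD of 1.64 and the share of this tissue in each sample is not known.

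Blood cell and leptomeningeal markers were lower in 5/6Nx. Fewer red cells alone, as in anaemia of kidney disease, stay open for the red cell markers but would not account for lower white cell markers. Of the 5 measured white cell members of the blood list 4 lay below 0, with a median of -1.28. This median was past the value set, after the result was seen, against fewer red cells alone, by more than the spread of 0.26. These members belong to the pattern and range from -4.39 (S100a9) to 0.03 (Cd3e). Their signal was low as a mean over both arrays, with 36.1% of measured genes dimmer, but this mean includes the lower 5/6Nx values. In sham S100a9 stood at 0.86 and Cd3e at 0.90, so neither was dim there. A further 9 red cell genes had a median of -0.08. Fewer blood cells of all kinds stay open as well. A second list of 16 leukocyte and platelet genes had a median of 0.00077, past the value set in advance against this explanation. That value was passed by less than the spread of 0.13, and the signal was low, since 32.3% of measured genes were dimmer. Members of the list split, with 8 above 0 and 8 below, from -1.96 (Gp9) to 1.01 (Treml1). Less leptomeningeal tissue in the 5/6Nx sample may explain part of the pattern, as a second list of 17 leptomeningeal genes had a median of -0.77. Lower expression within leptomeningeal cells would lower both leptomeningeal lists too, so the second list cannot tell it from less tissue. Whether 5/6Nx or the dissection set these differences was not tested.

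Heat shock genes were lower in 5/6Nx (median -0.71), while the cold-inducible RNA-binding protein genes Rbm3 (1.80) and Cirbp (1.81 at its brighter probe, -0.05 at the other) were higher, both named after their values were seen. A trend of the difference with signal is argued against by the median of -0.69 after the trend was removed. A lower tissue temperature before sampling is possible, and a second list of 22 heat shock factor targets had a median of -0.49, past the value set in advance for it. Any cause of lower heat shock factor activity would lower these targets too, so the list cannot single out temperature. Sampling at another clock time was not settled: 9 clock genes activated by Bmal1 exceeded 5 clock genes of the opposite phase by 0.78 in their medians (0.52 against -0.26), but the latter lay within the random range (percentile 8.45), Cry1 (0.08), Npas2 (0.24) and Per2 (-0.10) went against such a shift, and the 2 probes of Per1 stood at 1.33 and -0.02. With 1 array per group both explanations stay open, as does an effect of 5/6Nx itself, which was not tested.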
